A study of Mus musculus with 7 samples.

How the data were processed

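Small RNA of mouse CD4 T cells carrying the DO11.10 T cell receptor, which recognises an ovalbumin peptide, was measured on 7 custom Agilent arrays. Per the labels' protocols, total RNA was extracted with Trizol, 250 ng was named in the series' design text, and RNA was labelled with Cy3 using an Exiqon kit. The scanner files hold spot intensity on a linear scale, background-subtracted and spatially detrended by Feature Extraction but not normalized between arrays, per the file headers. The submitters' processing notes name version 10.6 of Agilent Feature Extraction, whereas the scanner files name version 9.5.1.1. The deposited value table of the whole series holds log2 values, whose equal medians (5.69 to 5.70) and shared maximum of 18.08 have the form of quantile normalization; the authors' background correction and the way spots were combined stay unknown. Of its 1776 rows, 4 matched a probe of the scanner files by identifier. Across the 7 arrays those 4 correlated with the quantile-normalized scanner values at r of 0.95, 0.48, 0.98 and 0.99. The table was therefore used as an alternative for counts of unnamed rows, without a detection filter. Spot flags of the scanner files were used as deposited.

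Each array held 13935 spots, of which 13118 were 7 spots for each of 1874 probes. Between 16.5% and 25.4% of these spots were well above background, no spot was saturated, and the number of arrays limits the precision. The files pair no probe with a miRNA name, and no table of miRNA sequences was used here. A tested feature may therefore be a small RNA other than a miRNA. Every probe ended in 10 T, and 1857 of the 1874 began with G. The target was taken as the reverse complement of the probe without these additions. Probes whose targets shared their start, with the shorter contained in the longer, were merged into 1 feature represented by the probe with the highest mean, which left 1753 features. Features are identified by target sequence, written as DNA. Positions 2 to 8 of the target are the seed, the part by which miRNAs are grouped into families. The family name of a seed is textbook background, not taken from the files, and members of a family, or the same miRNA of different species, cannot be told apart by it. The name lists fixed before the data were examined were translated to 84 seeds after the files were opened and before any signal was looked at. A target on a list shares a seed with a member, which does not show that it is that member or comes from the same cluster. A list may also miss members whose seeds were not among those translated. The seed shared by miR-130 and miR-301 was named after its values were seen. No filter on species was applied.

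Control spots and outlier-flagged spots were left out, spots of a probe were averaged as log2, and each array was scaled to its 75th percentile over the 253 probes detected on all 7 arrays. Detection required 50% of a probe's spots to be well above background. Features detected on every array of at least 1 group were tested, of which 214 were detected on all arrays. limma (version 3.58.1, in R 4.3.3) was fitted with lmFit and eBayes to all 7 arrays with group means, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A feature not well above background on any array of a group is given as "at least N-fold". There the mean of the bright group was set against the dim group's mean of, per array, the higher of the lowest signal well above background and the dim probe's own. The 17 seed lists were tested with camera at a preset correlation of 0.01 where at least 3 members were tested, which held for 12 lists, and again with an estimated correlation and with fry.

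The features named were chosen by a rule set at the same time as the name lists. It took up to 12 largest rises and 12 largest falls among adjusted p under 0.05 whose groups of arrays did not overlap. Where fewer than 5 passed, the 10 with the smallest p were added as values. It also took up to 4 members per list, and the brightest tested feature for the seeds of miR-155, miR-21, miR-146, miR-150, miR-181, miR-17, miR-92, miR-31, miR-10, miR-223 and miR-451. The text prints a part of these.

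On simulated data with known changes, 66.6% of changes of 2 log2 units were called in the comparison of WT host with naive and 73.8% in that of sOVA host with naive, over all features tested. Of unchanged features, 0.809% and 0.882% were called. The comparison of the hosts was simulated without changes only and gave 0 calls in 6840 tests. Simulated noise was independent between features and alike on all arrays. In the data arrays shared deviations, and log2 differences had an SD of 1.30 and 1.53 in replicate pairs with sOVA host replicate 3. Other replicate pairs had 0.60 to 0.77, so the simulated rates may not hold for these data. All arrays lay on 1 slide with 1 scan time. The position of each array on the slide, however, placed 4 in row 1 and 3 in row 2, and every group had arrays in both rows. Deviations from the group means correlated between arrays of different groups at 0.178 to 0.612 within a row. Because 2 groups hold 2 arrays each, the values across rows mirror these. Row was therefore fitted as a block and values are given within rows. Alternatives covered the background correction, scaling, detection filter, merging of probes, flags, pseudocount (16), prior, array weights, blocks and leaving out each array.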

Results

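The study compared small RNA in naive DO11.10 CD4 T cells with that in DO11.10 cells activated in mice of different kinds. Naive cells (2 arrays) were sorted as CD25 negative and CD44 low from mice with intact Rag2. Activated cells were sorted as CD44 high, 5 days after donor cells from Rag2-deficient mice had been moved into a host. That host was a Balb/c mouse described as wild type in the protocol (WT host, 2 arrays) or an sOVA mouse (sOVA host, 3 arrays). Hosts were immunized 24 h after transfer with activated dendritic cells loaded with ovalbumin peptide. The sample titles, however, read OVA immunized host for the WT host and sOVA immunized sOVA host for the sOVA host. Any difference in immunization could not be told apart from the host. The series title speaks of activation in vitro, while the design text and protocol describe activation in vivo. Cells came from pooled mice aged 6 to 8 weeks, and nothing in the labels says that replicates were separate pools, so p-values measure the spread between these samples, which may be technical. Naive and activated cells also differed in Rag2 genotype of the donor and in the sort.

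Between 309 and 467 of 1874 probes were detected per array. The 75th percentile of signal over probes detected on all arrays was 11870 and 15740 on the naive arrays. It was 9281 and 3591 on the WT host arrays, and 9860, 11110 and 2729 on the sOVA host arrays. WT host replicate 2 and sOVA host replicate 3 were thus the dimmest.

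**Figure D1:**
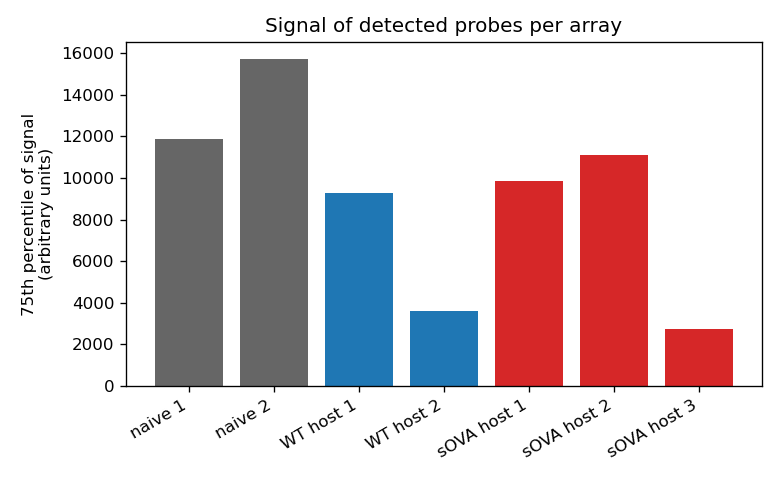
Bars give the 75th percentile of processed signal, in arbitrary units, over the probes detected on all 7 arrays, with naive arrays in grey, WT host in blue and sOVA host in red. WT host 2 (3591) and sOVA host 3 (2729) lay below the other 5 arrays.

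The first comparison asked which small RNA targets differ between naive cells and cells activated in a WT host. Targets with seeds of miR-183, miR-96 and miR-182 (a cluster), of miR-21 and of miR-130 and miR-301 were higher after activation. The miR-96 seed target TTTGGCACTAGCACATTTTTGCT (UC1004989) was not well above background on the naive arrays and was at least 15.2-fold higher in the WT host (adjusted p = 0.00107, limma). TTTGGCAATGGTAGAACTCACACCG, with the miR-182 seed, was at least 10.1-fold higher, and TATGGCACTGGTAGAATTCACT, with the miR-183 seed, at least 4.13-fold. The fitted log2 changes behind these bounds, 5.65 and 4.37, were 6.30 and 5.02 without naive replicate 1 and 5.01 and 3.73 without naive replicate 2, with both targets called. TAGCTTATCAGACTGATGTTGA (UC1004818), with the seed of miR-21, a miRNA known to rise in activated T cells, went from 0.86 ± 0.21 (SD, n = 2) to 4.23 ± 0.16 (SD, n = 2) in log2 units above the array's 75th percentile, 10.3-fold (adjusted p = 0.0017, limma). Of 8 tested targets with the seed shared by miR-130 and miR-301, a seed on no list and singled out after its values were seen, 7 rose: CAGTGCAATAGTATTGTCAAAGC by 12.5-fold, and CAGTGCAATGGTATTGTCAAAGC by at least 13.2-fold.

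The miR-155 seed target TTAATGCTAATTGTGATAGGGGT had a log2 change of 2.63 and the miR-146 seed target TGAGAACTGAATTCCATGGGTT one of 2.46 without passing (adjusted p = 0.0872 for each, limma), and both passed with slide row as a block (adjusted p = 0.0428 for each, limma).

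By fitted change, which is uncertain for dim targets, falls were led by CAGCAGCAATTCATGTTTTGGA (UC1005463), with the miR-15/16 seed. It had a log2 change of -3.80 ± 0.29 (SE, adjusted p = 0.00119, limma) and was well above background on 1 of 2 WT host arrays. TAGCAGCACGTAAATATTGGCG, with the same seed, had a change of -0.21 (adjusted p = 0.756, limma). Near-identical targets may share signal, so members of a seed are not independent. AACATTCAACGCTGTCGGTGAGT, with the seed of miR-181, which tunes T cell receptor sensitivity, fell by 3.34 on the log2 scale. TGTCAGTTTGTCAAATACCCCA (UC1005308), with the seed of miR-223, a myeloid miRNA, fell by 3.04 and was well above background on 1 of 2 WT host arrays. The miR-181 and miR-223 seed targets were not called when any single naive or WT host array was left out.

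In the fixed lists, 10 of 17 tested targets of the list of seeds raised by activation rose and none fell (13 rose when adjusted over the list alone), with a camera adjusted p of 8.32e-07. With an estimated correlation the adjusted p was 0.0892. Of 16 targets on the list high in naive cells, 4 fell (4 adjusted over the list alone; camera adjusted p = 0.00171, and adjusted p = 0.377 with an estimated correlation). TTCAAGTAATTCAGGATAGGT, with the miR-26 seed, was 2.83-fold lower (adjusted p = 0.0161, limma), while the miR-150 seed target TCTCCCAACCCTTGTACCAGTG had a change of -0.36 (adjusted p = 0.724, limma). Of 23 targets in the list of the miR-17 to miR-92 family 5 rose (5 adjusted over the list alone), among them TAAGGTGCATCTAGTGCAGTTAG of the miR-18 seed, 4.01-fold. The miR-17 seed target CAAAGTGCTGTTCGTGCAGGTAG had a change of 0.70 (adjusted p = 0.1, limma), and the list did not pass (camera adjusted p = 0.147). Of 6 miR-30 targets 1 fell (2 adjusted over the list alone), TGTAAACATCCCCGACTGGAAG, which fell by 2.19, and camera gave an adjusted p of 0.0161 (adjusted p = 0.495 with an estimated correlation). Of 15 let-7 targets 1 rose, TGAGGTAGTAAGTTGTATTGTT by 2.32-fold (0 adjusted over the list alone), against a list median of -0.44 (camera adjusted p = 0.0479, and adjusted p = 0.622 with an estimated correlation). The 3 miR-29 targets had a median of -2.13 with no member called (2 lower adjusted over the list alone; camera adjusted p = 0.0444, and adjusted p = 0.495 with an estimated correlation). Of 8 targets on the epithelial list 4 fell (4 adjusted over the list alone; camera adjusted p = 0.000535, and adjusted p = 0.0892 with an estimated correlation). Among them TAACACTGTCTGGTAACGATGT, with the seed of miR-200a and miR-141, was at least 1.45-fold lower, and was not called without naive replicate 1. The named miR-30 and let-7 targets were not called when any single naive or WT host array was left out (let-7 also without sOVA host replicate 1 or 2), and the miR-18 target was not called without naive replicate 1, naive replicate 2 or WT host replicate 2. Of 11 miR-15/16 targets 2 fell (3 adjusted over the list alone; camera adjusted p = 0.0161, and adjusted p = 0.495 with an estimated correlation). Of 19 targets on the list linked to regulatory T cells 3 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 0.0161, upward, and adjusted p = 0.495 with an estimated correlation). No target on the Sfmbt2 cluster list was called among 7 (median -1.10, camera adjusted p = 0.0177, and adjusted p = 0.525 with an estimated correlation). That list was read by seed and need not hold every member of the cluster, so called features outside it may belong to the cluster. None of 7 in the miR-23, miR-27 and miR-24 list (camera adjusted p = 0.226) or of 3 in the Dlk1-Dio3 list (camera adjusted p = 0.838) was called. Lists with fewer than 3 targets were given no camera test. The myeloid list held the miR-223 seed target alone, the erythroid list 2 targets and the liver, muscle and neural list 1, with 0 of these 3 called. The embryonic list of the miR-290 and miR-302 clusters held 1, with a change of 0.85 (adjusted p = 0.434, limma), and no endothelial or stromal target was tested. With slide row as a block, camera gave the 9 lists that passed adjusted p-values of 5.71e-06 to 0.0151, and each of these lists had a median of the same sign within both rows (activation list 2.42 and 2.82, naive list -1.32 and -0.986). With that block limma called 9 higher and 2 lower on the list linked to regulatory T cells, 7 lower on the naive list, 1 higher and 3 lower of let-7, 2 lower of miR-30 and 2 lower of miR-29. It also called 1 lower on the Sfmbt2 cluster list and 1 higher on the miR-23, miR-27 and miR-24 list.

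Altogether 64 features were called by limma (126 at an unadjusted p under 0.05), 44 higher and 20 lower, all with groups that did not overlap (259 features had such groups, 75.7%, where chance gives 33.3%). With slide row as a block 109 were called (72 higher, 37 lower). All 64 had the same sign within each row, but groups that do not overlap must give this, so it tests nothing. The median of all features was 0.27. Scaling to the 75th percentile of all probes moved it to -0.245 and gave 19 higher and 20 lower, so levels are relative to the array. Scaling to the median gave 33 and 25. Leaving out naive replicate 1 or 2 gave 12 or 18 calls, WT host replicate 1 or 2 gave 25 or 21, and sOVA host replicate 3 gave 160. Without both dim arrays, a choice made after seeing the data that leaves 1 WT host array, 125 were called.

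The second comparison asked the same for cells activated in an sOVA host. Targets of the miR-155 and miR-146 seeds were higher than in naive cells, together with the miR-21, miR-183, miR-96 and miR-182 seeds, and no difference between the hosts passed for any of them. TTAATGCTAATTGTGATAGGGGT, with the seed of miR-155, a miRNA needed for normal T cell responses, went from -3.30 ± 0.15 (SD, n = 2) to 0.75 ± 1.49 (SD, n = 3), 16.6-fold (adjusted p = 0.0222, limma). TGAGAACTGAATTCCATGGGTT, with the seed of miR-146, which restrains NF-kappaB signalling, went from -3.01 ± 0.68 (SD, n = 2) to 1.07 ± 1.26 (SD, n = 3), 16.9-fold (adjusted p = 0.0175, limma). Without sOVA host replicate 3 the log2 changes of these targets were 4.90 and 4.80, against 4.05 and 4.08 with it, and neither was called without naive replicate 1 or 2, nor that of the miR-155 seed without sOVA host replicate 1. Within slide rows 1 and 2 they were 4.79 and 2.46 for the miR-155 seed and 4.33 and 3.11 for the miR-146 seed. TAGCTTATCAGACTGATGTTGA of the miR-21 seed was 7.14-fold higher, and the miR-96 seed target at least 7.29-fold. AATGGATTTTTGGAGCAGG, whose seed is on no list, had the largest log2 change, 8.09 ± 1.20 (SE, adjusted p = 0.00905, limma), with 1 of 2 naive arrays well above background. It was 7.16 and not called without naive replicate 1, 9.03 without naive replicate 2, 9.0 without sOVA host replicate 2 and 7.09 without replicate 3. In the WT host the same target also had the largest rise among called features, 6.86 ± 1.31 (SE, adjusted p = 0.0152, limma). There it was not called when any single naive or WT host array was left out, with changes of 5.93 to 7.8.

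CAGCAGCAATTCATGTTTTGGA fell by 4.04 ± 0.27 (SE) on the log2 scale, with 1 of 3 sOVA host arrays well above background, and the miR-223 seed target fell by 2.68, with 2 of 3. The miR-26 seed target fell by 2.15, 4.42-fold, and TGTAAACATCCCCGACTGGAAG of the miR-30 seed fell by 1.78. The miR-223 and miR-30 seed targets were not called without naive replicate 1 or without naive replicate 2, and the miR-26 seed target was not called without naive replicate 1. The miR-150 seed target had a change of -1.97 (adjusted p = 0.0707, limma), and the brightest miR-181 seed target one of -1.64 (adjusted p = 0.0749, limma), which passed with slide row as a block. The miR-92 seed target TATTGCACTTGTCCCGGCCTGT had a change of -0.37 (adjusted p = 0.324, limma). No target of the miR-31 or miR-10 seed was tested.

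Of the 17 targets on the activation list 15 rose (16 adjusted over the list alone; camera adjusted p = 9.07e-09, and adjusted p = 0.0728 with an estimated correlation). Of 19 targets on the list linked to regulatory T cells 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.00127, and adjusted p = 0.461 with an estimated correlation). Its risers included the miR-155, miR-146, miR-21 and miR-182 seeds, which the activation list holds as well. In the miR-23, miR-27 and miR-24 list 2 of 7 rose, ATCACATTGCCAGGGATTTCCA by 2.72-fold (3 adjusted over the list alone; camera adjusted p = 0.245). Neither was called without naive replicate 1, naive replicate 2 or sOVA host replicate 2, nor the named target without sOVA host replicate 1. The naive list had 2 of 16 lower (1 adjusted over the list alone; camera adjusted p = 0.021, and adjusted p = 0.461 with an estimated correlation), and miR-30 had 2 of 6 lower (3 adjusted over the list alone; camera adjusted p = 0.0139, and adjusted p = 0.53 with an estimated correlation). No let-7 target of 15 was called (median -0.75, camera adjusted p = 0.0124, and adjusted p = 0.595 with an estimated correlation). Of 8 epithelial targets 2 fell (5 adjusted over the list alone, camera adjusted p = 0.0105, and adjusted p = 0.21 with an estimated correlation). Both had sOVA host means (-7.71 and -7.85) under the lowest signal well above background of each sOVA host array (-5.82, -7.03 and -5.20). No lower bound could be given for either fall. Of 23 targets of the miR-17 to miR-92 family 5 rose (5 adjusted over the list alone; camera adjusted p = 0.9). Of 11 miR-15/16 targets 2 fell (2 adjusted over the list alone, camera adjusted p = 0.236). Of 3 targets on the Dlk1-Dio3 list 2 fell (2 adjusted over the list alone, camera adjusted p = 0.162). Both were listed by the miR-329 seed, which does not place them in the cluster. The 3 miR-29 targets had a median of -1.75 with no member called (2 lower adjusted over the list alone; camera adjusted p = 0.116, adjusted p = 0.565 with an estimated correlation, and adjusted p = 0.0413 with slide row as a block). None of 7 targets on the Sfmbt2 cluster list was called (camera adjusted p = 0.162). With slide row as a block the 6 lists that passed had adjusted p-values of 3.67e-07 to 0.0126 by camera, and each had a median of the same sign within both rows (activation list 2.86 and 2.48, naive list -1.02 and -0.708). With that block limma called 8 let-7 targets, 2 miR-29 targets and 5 on the naive list lower, and 1 of the miR-17 to miR-92 family lower besides the 5 higher.

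In all, 72 features were called by limma (147 at an unadjusted p under 0.05), 53 higher and 19 lower, all with groups that did not overlap (211 features, 61.7%, where chance gives 20%). With slide row as a block 125 were called (78 higher, 47 lower). All 72 had the same sign within each row, which again follows from groups that do not overlap. The median of all features was 0.11, and the 75th percentile of all probes moved it to -0.704 with 24 higher and 44 lower. Quantile normalization gave 34 and 28. Leaving out naive replicate 1 or 2 gave 11 or 13 calls, and sOVA host replicate 3 gave 131. Without both dim arrays 156 were called.

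Markers of other cells varied between arrays. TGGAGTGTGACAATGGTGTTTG, with the seed of the liver miRNA miR-122, was at 0.50 on sOVA host replicate 3, against -1.64 and -9.05 on replicates 1 and 2, and at -6.45 and -3.26 on the WT host arrays and -9.29 and -10.59 on the naive arrays, where it was not well above background. It was at least 6.77-fold higher in the WT host than in naive cells and at least 18.6-fold in the sOVA host, without passing (adjusted p = 0.261 and 0.124, limma). AAACCGTTACCATTACTGAGTTT, with the seed of the erythroid miRNA miR-451, was at 0.94 on replicate 3, against -1.09 and -4.12 on replicates 1 and 2, -3.33 and -1.80 on the WT host arrays and -0.97 and -1.84 on the naive arrays (adjusted p = 0.599 and 0.993 for the hosts against naive, limma).

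**Figure D2:**
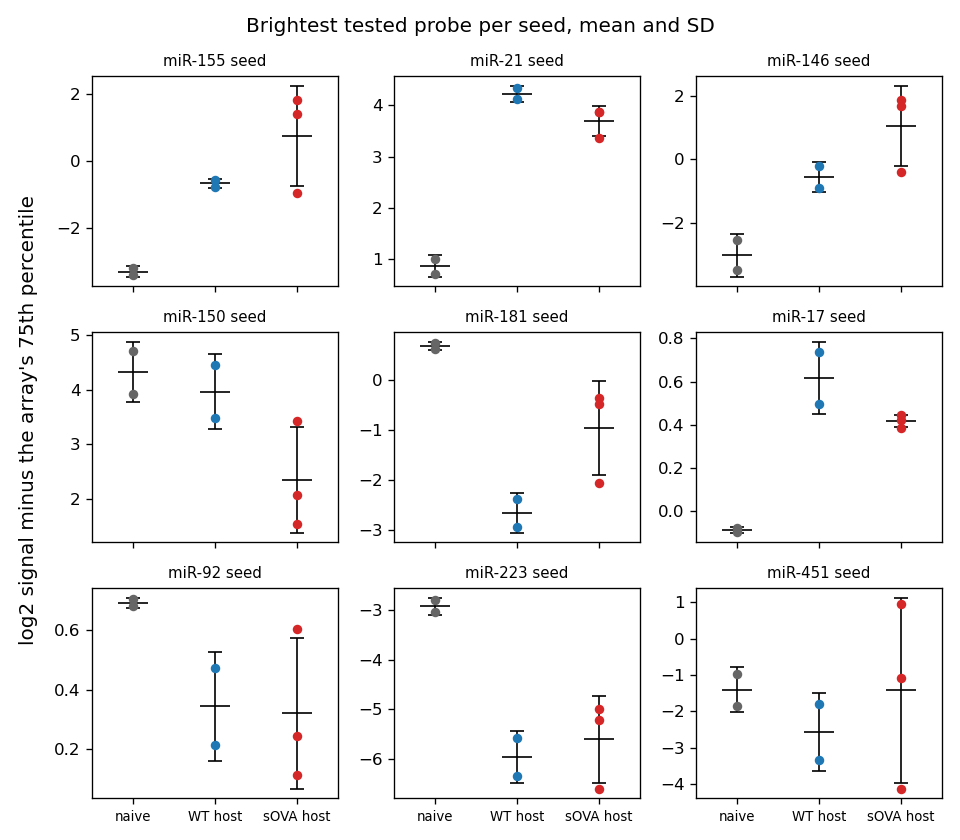
Each panel gives, for the brightest tested target of a seed, the log2 signal above the array's 75th percentile on each array (points), with group mean and SD (black). The miR-155 and miR-146 seed values of sOVA host replicates 1 and 2 lay above all WT host arrays, while replicate 3 did not.

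The changes from naive in the hosts were alike across features, with Pearson r = 0.898 across the features tested, which are not independent replicates. Both comparisons used the naive arrays, and simulated unchanged groups gave a mean r of 0.546 (95% of simulations between 0.396 and 0.67). That simulation drew noise independently, whereas WT host replicate 2 and sOVA host replicate 3 deviated together. The covariance was 2.3 against a simulated 0.194, a difference of 2.11. Of the calls, 38 were higher in both, 12 lower in both and 0 opposite, where independent lists would share 6.82 and 1.11. A split of the naive arrays would leave 1 for each comparison and was not made, so part of the excess in r and in shared calls may come from sharing them.

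**Figure D3:**
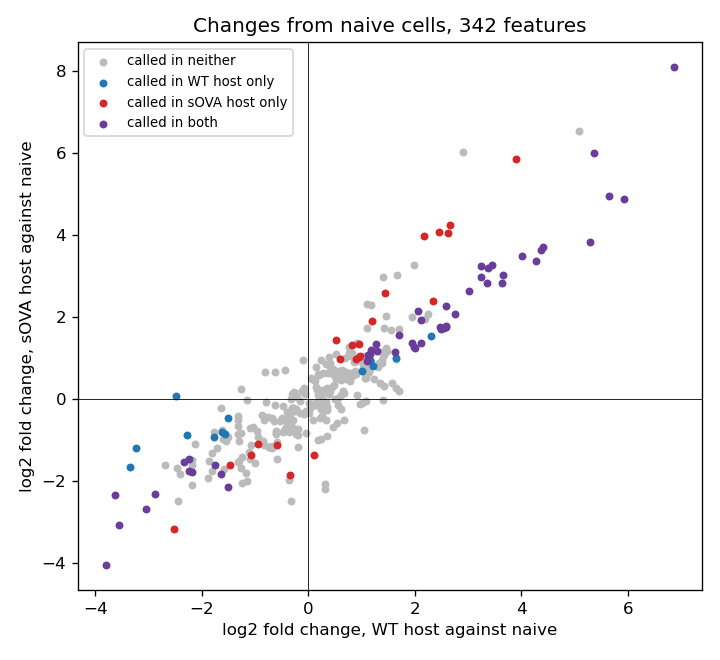
Each point is a tested feature, with its log2 fold change against naive in the WT host (x axis) and the sOVA host (y axis), coloured by the comparisons in which it was called. The 38 features higher in both and the 12 lower in both lie in the upper right and lower left.

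The third comparison asked whether the small RNA targets of activated cells differed between the hosts. No feature was called by limma, 0 in all, with 41 at an unadjusted p under 0.05 and a smallest adjusted p of 0.331. The median of all features was -0.147, and 80 features had groups that did not overlap (23.4%, where chance gives 20%). Adjusted over the list alone, 2 of 3 targets on the Dlk1-Dio3 list were lower in the sOVA host. On the naive list 1 of 16 and on the list linked to regulatory T cells 1 of 19 were higher, and 0 on every other list tested. The largest difference among the 10 smallest p-values was that of TCCCTGAGACCCTTTAACCTGTGA of the miR-125 seed. It was not well above background on the WT host arrays, was so on 1 of 3 sOVA host arrays, and was at least 1.42-fold higher there (adjusted p = 0.331, limma). It was the target higher on the naive and regulatory T cell lists. The miR-155 seed target had a difference of 1.42 ± 0.81 (SE, adjusted p = 0.574, limma). The miR-146 seed target had 1.62 ± 0.75 (SE, adjusted p = 0.449, limma), and the miR-150 seed target -1.61 ± 0.64 (SE, adjusted p = 0.391, limma). These 3 differences lay in slide row 1, at 2.37, 2.68 and -2.63, and not in row 2, at -0.383, -0.162 and -0.0544, where sOVA host replicate 3 and WT host replicate 2 were compared. Camera passed 3 lists: the miR-17 to miR-92 family with all 23 targets lower (adjusted p = 0.00122), epithelial (adjusted p = 0.0138) and miR-15/16 (adjusted p = 0.0332) higher. With an estimated correlation the adjusted p-values were 0.603, 0.405 and 0.603, and with row as a block 0.0042, 0.0334 and 0.0794. The let-7 list, with all 15 targets lower and a median of -0.288, had a camera adjusted p of 0.15, adjusted p = 0.849 with an estimated correlation and adjusted p = 0.0255 with row as a block, and medians of -0.302 and -0.417 within rows 1 and 2. The Dlk1-Dio3 list, with 3 of 3 targets lower and a median of -1.47, had a camera adjusted p of 0.0544, adjusted p = 0.45 with an estimated correlation and adjusted p = 0.0863 with row as a block, and medians of -1.90 and -0.953 within rows. Within slide rows 1 and 2 the list medians were -0.294 and -0.66 for the miR-17 to miR-92 family, 0.612 and 0.859 for the epithelial list, and 0.651 and -0.314 for miR-15/16. With 75th-percentile scaling over all probes camera passed 0 lists.

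The count of 0 depended on the arrays and values used. Without sOVA host replicate 3, 70 features were called (42 higher, 28 lower), among them the miR-155 seed target (2.27), the miR-146 seed target (2.34) and the miR-150 seed target (-2.15). Array weights gave 47 calls, the slide row block 0, and the removal of both dim arrays, with 1 WT host array left and assumed to vary like the others, 49. The authors' deposited value table, of whose 1776 rows only 4 matched a probe, gave 126 of 1775. No detection filter was applied to that table, and the scanner values without the filter gave 0 of 1753.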

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

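The tests on slide row, on the dim arrays and on sOVA host replicate 3 were chosen after the results were seen, and the test on mismatch spots was set before.

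Control spots outside the comparisons carried signal. The arrays held 281 spots whose probes differ from 13 parent probes by 1 mismatch. Of these spots over the 7 arrays, 58.9% were well above background, against 0.928% of the 77 hairpin negative controls. The change from naive of the mismatch spots followed that of the parents with a Spearman rho of 0.967 across the 13 parents, so binding of the parent's target is a candidate explanation. Targets that differ by a base may therefore share signal. No biological explanation was tested.

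WT host replicate 2 and sOVA host replicate 3 were dim, lay in slide row 2 and deviated together (r = 0.612 across features). Their values correlated at 0.969. Values of sOVA host replicate 3 correlated at 0.909 and 0.878 with sOVA host replicates 1 and 2, and at 0.900 with WT host replicate 1. Slide row may contribute: the listed seeds of naive replicate 2, in the same row, lay -0.174 relative to the other probes against naive replicate 1, which decided nothing. A smaller share of miRNA in the labelled RNA is another candidate. Listed seeds fell further than other probes by a difference of -0.33 on WT host replicate 2 and -1.13 on sOVA host replicate 3. Beyond the naive value, the upper bootstrap bound was -0.744 on the latter but 0.0156 on the former. A seed on no list can still belong to a miRNA, as that of miR-130 and miR-301 does. The values thus compare listed with unlisted seeds and cannot measure a share of miRNA, so this stays open.

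Between the hosts 0 features were called (41 at an unadjusted p under 0.05, limma), against 70 without sOVA host replicate 3 and 47 with all arrays under array weights. Spread from the dim arrays may account for it, since 49 features were called without both, which leaves 1 WT host array, yet 0 (63 at an unadjusted p under 0.05, limma) with them as a block. A wrong label is another candidate explanation: of 70 features called without this array, 56 (80%, exact binomial 95% interval 68.7 to 88.6) had its value nearer the WT host mean, but these features had been picked on the other arrays, which favours that outcome, and the bound of 80% was first met exactly, with the demand that the interval exceed it added once the share was known, so the test decides nothing. RNA of other cells may be present, as 3 of 3 tested erythroid and liver seed targets were highest on this array, seen before the test was written, although the cells had been sorted, and presence does not show that it removed any call. A difference between the hosts stays open, untested beyond these values.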

How the results depend on the processing

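The added settings (without both dim arrays, dim arrays as a block, percentile over listed seeds) were chosen after seeing the data. No named feature or list that passed both as reported and under an alternative had opposite signs. Of the 64 features called for WT host against naive, 62 had the same sign with normexp, and under the other settings all of those tested did, as did all of the 72 for sOVA host against naive (the value table was not compared by feature). The cause of the shifts below was not tested, except that fewer arrays or features enter some of them.

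Calls of WT host against naive (64) became 41 with normexp, 39 with the percentile over all probes, 16 without a filter on dim probes, 25 with features detected on all arrays, 129 with the arrays of the 2 groups alone, 159 with array weights, 109 with the slide row as a block, 125 without both dim arrays and 225 in the authors' value table. Calls of sOVA host against naive (72) became 25 without the filter, 34 with detection on all arrays, 181 with array weights, 125 with the slide row, 156 without both dim arrays, 121 with dim arrays as a block and 212 in the value table. Calls between hosts (0) became 47 with array weights, 49 without both dim arrays and 126 in the value table. Leaving out each array gave 12 to 160, 11 to 131 and 0 to 70 calls, and a lone array of a group is then assumed to vary like the others.

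Whether replicate numbers pair the samples could not be decided. Deviations of same-numbered arrays correlated at -0.597 to 0.346. Pairs in the same slide row had 0.194 to 0.346, and those in different rows -0.597 and -0.178. Deviations mirror each other within the naive and the WT host arrays, so these values cannot separate pairing from slide row. With a replicate block, calls became 139, 104 and 27, lists shifted between hosts 7, and r 0.824. Replicate number 3 occurs in the sOVA host alone, so this block fits that array exactly and removes it from the comparisons. Leaving out sOVA host replicate 3 without a block gave 160, 131 and 70 calls. The higher counts with the block need not come from pairing.

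Lists shifted numbered 9, 6 and 3 in the 3 comparisons. For WT host against naive they became 5 with detection on all arrays, 5 with dim arrays as a block and 0 with an estimated correlation. For sOVA host against naive they became 3 with quantile normalization and 0 with an estimated correlation. Between hosts they became 0 with the percentile over all probes, 5 without the filter, 1 with detection on all arrays, 5 with the mean over probes, 5 with each probe its own feature, 6 with array weights, 8 with the percentile over listed seeds and 0 with an estimated correlation. Leaving out each array gave 6 to 10, 2 to 8 and 1 to 7 lists. A different test, fry, which asks whether a list moves one way and not whether it stands apart from other features, passed 5, 4 and 2 lists, among the 5 the miR-17 to miR-92 family, which camera did not pass.

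The similarity r of 0.898 was 0.806 to 0.929 when each array was left out and 0.744 without both dim arrays. Signal over background limits what could be tested; of 1753 features, 214 were detected on all arrays.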

Other observations

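These values come from the planned comparisons, and no test was added for them. Targets outside the lists changed in both hosts. TGGATTTTTGGATCAGGGA was not well above background on the naive arrays and was at least 8.21-fold higher in the WT host and at least 12.8-fold in the sOVA host. It was not called in the WT host when any single naive or WT host array or sOVA host replicate 1 was left out, with fitted log2 changes from 4.72 (without naive replicate 2) to 6.01 (without naive replicate 1). In the sOVA host it was not called without naive replicate 1 (6.65), naive replicate 2 (5.35) or sOVA host replicate 1, and its fitted change was 7.13 without sOVA host replicate 2 and 4.80 without replicate 3. TTATAAAGCAATGAGACTGATT was well above background on the naive arrays alone and was at least 3.69-fold and at least 2.28-fold lower, the latter not called without naive replicate 1 or 2. GTTGGAGGATGAAAGTACGGAGTGAT fell by 2.23 and by 1.74 on the log2 scale (limma adjusted p = 0.0115 and 0.0222). It was not called in the WT host when any single naive or WT host array was left out, nor in the sOVA host without naive replicate 1, naive replicate 2 or sOVA host replicate 2. In the Dlk1-Dio3 list, AACACACCTGTTCAAGGATTCA, with the miR-329 seed, fell by 1.84 in the sOVA host (limma adjusted p = 0.027). It had a change of -0.34 in the WT host (limma adjusted p = 0.599), and the difference between the hosts did not pass over all features (limma adjusted p = 0.331). The seed alone does not show that this target is miR-329 or comes from the Dlk1-Dio3 cluster. The fall in the sOVA host was not called without naive replicate 1, naive replicate 2, sOVA host replicate 1 or sOVA host replicate 2. Adjusted over the list alone, this target and AACACACCTATTCAAGGATTCA, which shares its seed and may share its signal, were lower in the sOVA host than in the WT host, at -1.90 and -1.28 within slide rows 1 and 2 for the former and -1.96 and -0.953 for the latter. By fry, which tests whether a list moves one way and not whether it stands apart from other features, the list was lower between the hosts (adjusted p = 0.0367), while camera did not pass it (adjusted p = 0.0544, and 0.45 with an estimated correlation).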
